A study of Homo sapiens with 2 samples.

How the data were processed

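Gene expression was measured by RNA sequencing in 2 diploid human embryonic stem cell lines, HuES53 and HuES64, with 1 library per line. Per the labels, both lines were undifferentiated, came from embryos made by in vitro fertilization, and served as controls. Polyadenylated RNA was selected and the libraries were made with an Illumina TruSeq RNA kit, per the labels' protocols. The submitters' processing notes name TopHat2 2.0.4 and Cufflinks 2.0.2, without saying what each was used for. The genome build, the gene annotation, the strand setting and any filter on reads are not given in the sources used here.

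The authors deposited 1 table of FPKM values, that is, fragments scaled by transcript length and by the number of mapped fragments, with 25593 rows. Each row gives a gene symbol, a locus and 1 value per line, and no column belonged to another sample. Loci in the table count from 0: of 1299 microRNA genes compared with a reference annotation, 1264 had the same length on that reading. Coordinates are printed counting from 1, in the build of the deposited table, and were not converted. FPKM values are not counts, so no count test was used. An exact 0 in such a table can be a failed estimate, so a gene at 0 is described as listed at 0 and no fold is given for it.

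The 136 rows on chromosome Y were left out. Rows that shared a symbol were summed (21 symbols), which left 25434 symbols. A difference is log2(FPKM + 1) in HuES53 minus the same in HuES64, for the 13790 genes with a mean of at least 1 FPKM over the lines. The pseudocount of 1 FPKM makes the folds printed here smaller than the plain ratio, most of all for low genes. Because each line has a single library, there is no replicate error, no p-value is given, and every difference describes these 2 libraries, not the lines as such. Genes were counted at 2-fold and 4-fold sizes.

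A total of 35 gene lists was fixed before the data were examined, and 31 had at least 5 members with a mean of at least 1 FPKM. For each of these the median difference was set against 10000 random lists of the same size, drawn from the same genes in 20 bins of mean expression. Draws within a bin were made with replacement, a choice made for speed. A list is called outside when its median lies beyond the central 95% of the random medians. Chance would give this for 1.55 of 31 lists if genes varied independently. Genes of the same list can vary together, so the true chance rate may be higher. The genes of each autosome were compared with 10000 random gene sets in the same way. Genes named in the text follow a rule that was also fixed beforehand. It takes the 15 largest differences in each direction among genes above 0 in both lines, and the 5 highest genes of each line that are listed at 0 in the other, if at 5 FPKM or more. From each list it takes the 3 members with the highest mean, the 3 with the largest difference and any member at least 2-fold different. XIST, TSIX, Y-linked genes, HLA genes and genes often deleted whole in healthy people were never named. Genes named outside the rule are marked as such, and some genes that the rule would name are not reported here.

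Depth was estimated from the steps of the values. Among olfactory receptor genes with loci under 1100 bases and under 6 fragments, 18 of 21 values in HuES53 and 9 of 12 in HuES64 fell within 3% of a whole number of fragments, for an assumed mean fragment length of 200 bases. The step of each line was found by a search that kept the size with the largest share. These shares are therefore fitted best values on few genes and no separate evidence for the depth. The steps put the depth of HuES53 at 1.22 times that of HuES64. By this estimate 1 FPKM over 1 kb stands for 18.5 fragments in HuES53 and 15.2 in HuES64, which covers counting error only. The absolute depth depends on the assumed fragment length.

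The GC content and length of each gene's transcripts came from GENCODE release 29 and were matched by symbol for 11921 genes, 86.4% of those tested. No coordinates were taken from it. To remove a trend, medians over 20 bins of GC content and 20 bins of length were subtracted in 5 rounds. For summed FPKM of ZNF genes the same trend was divided out of the HuES53 values. Genes whose loci overlap another gene, or span under 300 bases, were marked, since fragments of overlapping genes and of near-identical copies cannot be told apart in such a table. The text does not flag the overlap of every gene it names. The alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5 FPKM, no filter, a mean of at least 5 FPKM, 3 further scalings (upper quartile, median of ratios, TPM), keeping the highest row of a repeated symbol, thresholds of 0.1 and 5 FPKM for detection, and random lists in 10 bins or without matching. The alternatives chosen after seeing the data were the removal of the GC and length trend, with the median or the longest transcript of a gene, leaving out short or overlapping loci, and random lists matched on GC content.

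The code was tested on simulated data for HuES53 against HuES64. Fragments were drawn at the estimated depth, with the length of each gene's longest transcript, for 11897 genes, 200 of them chosen to be changed. Shorter transcripts would give fewer fragments and more counting error. At the 2-fold size it found 96.0% of the genes changed 4-fold and 89.9% of those changed by 1.5 on the log2 scale, and 6 unchanged genes (0.051%) passed from counting error alone. Of 200 lists of genes drawn at random, 4.5% fell outside, which is near the set rate by construction. This says nothing of lists whose genes vary together. The programs were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.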

Results

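The series belongs to a study that derived haploid human embryonic stem cells. The 2 libraries analysed here came from its diploid control lines, HuES53 and HuES64, each derived from an embryo made by in vitro fertilization and kept undifferentiated. Polyadenylated RNA was sequenced from 1 library of each line, so there are no replicates, and a difference between the lines has no replicate check. The comparison open to these data is how alike the controls were and which genes set them apart. Steps fitted to a few low values gave an apparent depth 1.22 times higher in HuES53, where 1 FPKM over 1 kb stood for about 18.5 fragments, against 15.2 in HuES64. At or above 1 FPKM, 13790 genes were detected in HuES53, 13570 in HuES64 and 13129 in both.

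Most genes had similar levels in the lines. Across the 13790 genes with a mean of at least 1 FPKM, Pearson's r of log2(FPKM + 1) was 0.958 and Spearman's rho was 0.952, genes not being independent replicates. A total of 96.1% of these genes differed by less than 2-fold, and the standard deviation of the differences was 0.56. At least 2-fold higher in HuES53 were 297 genes, and 235 were at least 2-fold higher in HuES64. At 4-fold the counts were 60 and 46, or 29 and 20 without loci under 300 bases. With a pseudocount of 0.1 FPKM the 2-fold counts were 585 and 405, and among the 9661 genes with a mean of at least 5 FPKM they were nearly equal, at 161 and 159. For the 11921 genes with a reference transcript they were 245 and 170, and 219 and 132 once the GC and length trend described next was removed. TPM scaling, which divides by the sum of each library (601128 FPKM in HuES53 and 713421 in HuES64), moved the median difference of all genes from 0.03 to 0.25. With it the counts were 774 and 200, so that 79.5% of the 2-fold genes were higher in HuES53, against 55.8% with the deposited values. The 100 highest genes of each line held 28.2% of the FPKM sum in HuES53 and 34.1% in HuES64. Differences tended lower for highly expressed genes, as random lists matched on expression show. Their typical median was -0.26 for the ribosomal protein list and 0.10 for the naive pluripotency list. The difference also depended on GC content and transcript length. Its median fell from 0.30 in the tenth of genes lowest in GC (median 38.7%) to -0.31 in the tenth highest (64.3%), with a Spearman's rho of -0.49 across genes. Over 10 equal groups by transcript length it was lowest, at -0.10, in the fifth (median 927 bases) and highest, at 0.28, in the group of longest transcripts (4132 bases), with a rho of 0.16.

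Both lines expressed the genes of pluripotent cells at high levels. POU5F1, the core transcription factor of pluripotency, stood at 1053 FPKM in HuES53 and 1381 in HuES64. TDGF1, a co-receptor for Nodal, stood at 723 and 528 FPKM, and the neuropeptide gene GAL at 807 and 835. NANOG (94.4 and 84.7 FPKM) and SOX2 (114 and 122 FPKM), also core factors but named outside the fixed rule, were nearly level. As a group, the 28 core pluripotency genes were higher in HuES53, with 21 of 28 above 0 and a median difference of 0.37, above all 10000 random lists. POU5F1 (1.31-fold) was among the 7 members higher in HuES64. The largest differences in the list were DPPA2 (36.4 against 16.4 FPKM, 2.15-fold), ESRG (706 against 355 FPKM) and TERF1, a telomere-binding protein gene (279 against 141 FPKM). ESRG overlaps another gene in the table.

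Genes of the naive and primed forms of pluripotency lay inside their random lists, but not under every alternative. The naive list had a median of 0.41 over 11 members, at the 97.0 percentile of random lists and thus just inside. FGF4, a growth factor gene (2.73 against 0.514 FPKM), was its only member at least 2-fold different. The highest naive members were TFAP2C (21.1 and 20.4 FPKM), NLRP7 (6.10 and 3.32 FPKM) and DPPA5 (4.60 and 3.03 FPKM). The naive list moved outside under 6 of the alternatives, among them both smaller pseudocounts. The primed list had a median of 0.12 over 15 members, with THY1 at 243 and 227 FPKM and ETV5 at 33.0 and 17.8 FPKM. It lay above its random lists with the trend removed (0.20, or 0.25 by the longest transcript).

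Most endoderm genes were higher in HuES53. Of the 16 endoderm genes, 12 were higher there, with a median difference of 0.35 at the 99.6 percentile of random lists. CER1, which encodes a secreted inhibitor of Nodal and BMP, stood at 543 FPKM against 104 (5.19-fold). The chemokine receptor gene CXCR4 stood at 68.1 against 26.3 FPKM, HHEX at 7.81 against 3.14, and AFP, which encodes alpha-fetoprotein, at 7.25 against 1.53. The apolipoprotein genes APOA2 (264 and 214 FPKM) and APOA1 (113 and 152 FPKM) differed less, and the endoderm factor SOX17, named outside the rule, went the other way (6.89 against 10.6 FPKM). With the GC and length trend removed, the endoderm median was 0.56. The mesoderm list also lay above its random lists, with a median of 0.56 over 9 members, 6 of them higher in HuES53. MIXL1 stood at 6.84 against 2.52 FPKM and GSC at 10.7 against 4.90 FPKM, while BMP4 was lower (10.7 against 17.2 FPKM). With no filter on low genes, the mesoderm median was 0.29, still above its random lists.

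Single genes of the Nodal pathway were higher in HuES53, while BMP target genes were higher in HuES64. LEFTY2, a Nodal inhibitor that Nodal signalling itself induces, stood at 623 FPKM in HuES53 and 163 in HuES64, NODAL at 47.2 and 21.5 FPKM, and SKIL at 35.5 and 10.7 FPKM. These 3 were at least 2-fold higher in HuES53, and LEFTY1 stood at 454 and 302 FPKM. The whole Nodal and TGF-beta list of 12 had a median of 0.10, inside its random lists. All 6 BMP target genes were higher in HuES64 (5 of 6 with TPM scaling), with a median of -0.68 at percentile 0.03, and -1.04 among those with a mean of at least 5 FPKM. ID1 stood at 108 FPKM in HuES53 and 246 in HuES64, ID2 at 8.69 and 21.9, ID3 at 23.04 and 48.39, and BAMBI at 33.8 and 42.5 FPKM.

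**Figure D1:**
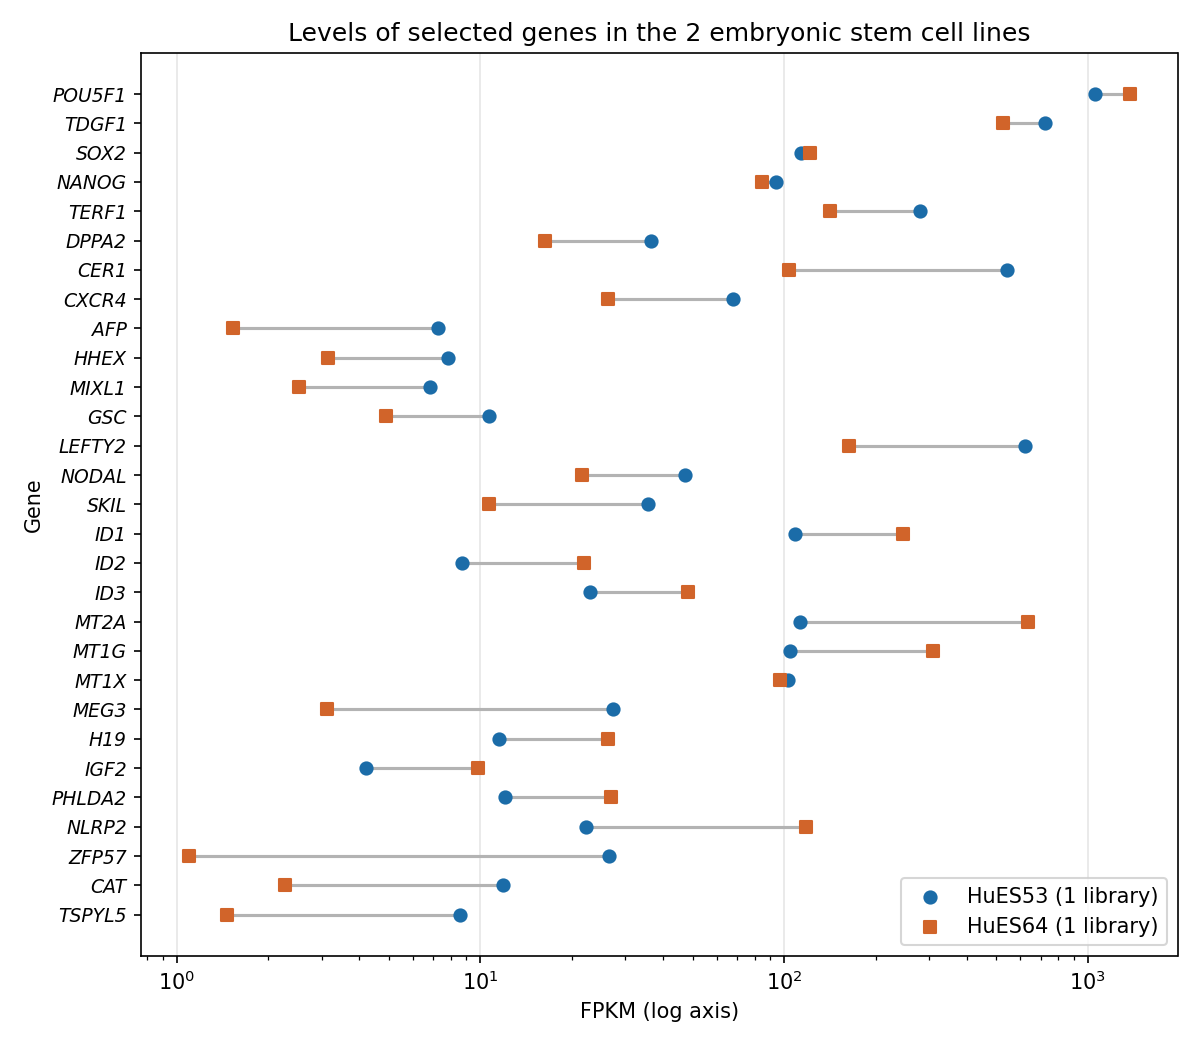
FPKM (horizontal, log axis) of selected genes (vertical) in HuES53 (circles) and HuES64 (squares), 1 library each, so no error can be drawn. SOX2 and NANOG lie close together, and POU5F1 lies somewhat higher in HuES64 (1381 against 1053 FPKM). CER1 and LEFTY2 lie higher in HuES53 (543 against 104 and 623 against 163 FPKM). MT2A and ID1 lie higher in HuES64 (635 against 113 and 246 against 108 FPKM).

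Markers of other cell types were mostly low, apart from those of fibroblasts and mesenchyme. The median FPKM over all listed genes was 0.117 and 0.127 for neuroectoderm, 0.201 and 0.120 for blood and endothelium, and 0.232 and 0.0185 for germ cells, in HuES53 and HuES64. Too few members reached 1 FPKM in these 3 lists to set them against random lists. TUBB3 (264 and 285 FPKM) and NES (66.3 and 71.0 FPKM), genes of neural progenitors and neurons, were high in both lines. Among germ cell genes DND1, which overlaps another gene, stood at 5.92 and 5.06 FPKM, DAZL at 1.89 and 3.86, and PIWIL2 at 1.51 and 0.0189. TEK (4.11 and 4.09 FPKM) led the blood and endothelium list. The neural crest median was -0.02, with ETS1 at 20.95 and 11.73 FPKM, and the trophectoderm median was 0.18, with IGFBP3 at 12.6 and 6.10 FPKM. The trophectoderm list was outside, at 0.64, with the trend removed by the longest transcript. CGA, a hormone subunit gene of the trophoblast, stood at 2.90 FPKM in HuES53 and was listed at 0 in HuES64. Fibroblast and mesenchyme genes were higher in HuES64 in 12 of 17 cases, with a median of -0.38 at percentile 0.25. The median over all 20 listed genes was 7.11 FPKM in HuES53 and 8.55 in HuES64. SPARC stood at 273 and 236 FPKM, and COL1A1 at 138 and 168. TAGLN stood at 779 FPKM in HuES53 and 1165 in HuES64, and COL6A2 at 66.5 and 121. COL3A1 stood at 3.08 and 8.00 FPKM, and COL5A2, in the other direction, at 28.56 and 14.005. The fibroblast and mesenchyme median was -0.20 with the GC and length trend removed, and with a mean of at least 5 FPKM (-0.33) the list was no longer outside. COL3A1, COL5A2, SPARC and TEK overlap other genes in the table.

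Ribosomal protein genes were higher in HuES64. All 79 were higher there (78 of 79 with TPM scaling), with a median difference of -0.64 against a random interval of -0.35 to -0.15. The median FPKM of the list was 1081 in HuES53 and 1755 in HuES64. The highest of the 20 expression bins also holds lower genes, so the matching on expression is loose for this list. RPL37A stood at 3778 FPKM in HuES53 and 6301 in HuES64, RPS29 at 3640 and 5384, and RPLP1 at 3604 and 5139. RPS26 differed by 2.22-fold (138 against 307 FPKM), and RPL36A, which overlaps a read-through gene, by 5.73-fold (2.64 against 19.9 FPKM). Many ribosomal protein genes have pseudogene copies, so the value of a single member is uncertain. Nuclear genes of oxidative phosphorylation leaned the same way, with 69 of 76 higher in HuES64 (55 of 76 with TPM scaling), a median of -0.34 and a random interval of -0.31 to -0.10. That median was -0.09 with TPM scaling (-0.37 before and -0.35 after it relative to all genes), and -0.16 with the trend removed by the longest transcript, outside in both cases. Removal of the trend covered 61 of the 76 members, as the ATP synthase genes had no matched transcript. COX7C, of cytochrome c oxidase, stood at 1430 and 2070 FPKM, NDUFA13, of complex I, at 496 and 871, and NDUFA11 at 136 and 242. No member was 2-fold different. The 13 mitochondrially encoded genes were not analysed here.

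Metallothionein genes, which encode small metal-binding proteins, made the list with the largest difference. Of 8 members, 7 were at least 2-fold higher in HuES64, and the median was -1.74, below every random list. MT2A stood at 113 FPKM in HuES53 and 635 in HuES64, MT1G at 105 and 308, MT1H at 65.6 and 194, MT1E at 41.6 and 161, and MT1M at 10.6 and 54.8. MT1F (43.2 and 93.3 FPKM) and MT1A (0.857 and 8.03 FPKM) followed. With the GC and length trend removed, MT1F fell just under 2-fold (-0.997). MT1X, named outside the fixed rule as the exception, stood at 103 and 97.1 FPKM. These genes are close copies, so the value of a single member is uncertain.

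Cell cycle genes were higher in HuES53 in 20 of 29 cases, with a median of 0.35 above every random list. TOP2A, the topoisomerase of dividing cells, stood at 102 against 53.9 FPKM, the mitotic checkpoint gene BUB1B at 72.8 against 35.3, and KIF11 at 27.7 against 14.8. PCNA (231 and 226 FPKM) and CDC20 (180 and 181 FPKM) were level, and CCNB1 stood at 204 and 160. With the GC and length trend removed, the cell cycle median was 0.21, and without overlapping genes it was 0.20. Heat shock genes had a median of 0.32, with 9 of 12 higher in HuES53, among them HSPA8 (1164 against 839 FPKM), HSP90AA1 (626 against 446 FPKM) and HSPA1B (64.4 against 34.1 FPKM). Cholesterol synthesis genes had a median of 0.24, with 18 of 22 higher in HuES53. The sterol carrier gene STARD4 stood at 8.61 against 3.19 FPKM, and HMGCS1, an early enzyme of the pathway, at 58.6 against 32.4. FDPS went the other way (141 against 174 FPKM). Without matching of the random lists on expression, this list was not outside. Of the genes named in this paragraph, BUB1B, PCNA, HSPA8, STARD4 and FDPS overlap other genes in the table.

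Structural non-coding RNAs were higher in HuES64, with 7 of 8 members and a median of -0.93. RN7SL2, an RNA of the signal recognition particle, stood at 157 and 301 FPKM, RN7SK at 21.1 and 37.4, SNORD3A at 8.32 and 34.2, and RPPH1 at 1.21 and 9.35. RNU4-2 went the other way, at 11.7 FPKM in HuES53 and listed at 0 in HuES64. With the trend removed the median was -0.61, or -0.32 by the longest transcript. Most of these RNAs carry no poly(A) tail, and several have copies elsewhere in the genome.

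Imprinted genes differed most in single genes. The 14 maternally expressed genes had a median of -0.02, and the 17 paternally expressed genes had a median of 0.03, both inside. With a mean of at least 5 FPKM the maternally expressed genes had a median of -0.49, below their random lists. MEG3, a maternally expressed long non-coding RNA of chromosome 14, stood at 27.3 FPKM in HuES53 and 3.13 in HuES64. Higher in HuES64 were H19 (11.5 against 26.2 FPKM), PHLDA2 (12.04 against 26.96 FPKM), NLRP2 (22.2 against 118 FPKM) and the paternally expressed growth factor gene IGF2 (4.19 against 9.83 FPKM). With the GC and length trend removed, the differences of H19 (-0.74), PHLDA2 (-0.73) and IGF2 (-0.94) were under 2-fold. MEG3, H19 and IGF2 overlap other genes in the table. SNURF (1117 and 1347 FPKM), MEST (94.1 and 70.9 FPKM) and PEG10 (44.7 and 23.8 FPKM) differed by under 2-fold. ZFP57, which encodes a zinc finger protein that maintains methylation at imprinted regions, stood at 26.6 FPKM in HuES53 and 1.09 in HuES64. Its list, DNA methylation and Polycomb genes, had a median of 0.19, inside, with TRIM28 at 360 and 388 FPKM. Of 7 expressed genes known to vary between pluripotent lines, 3 were at least 2-fold higher in HuES53, namely the catalase gene CAT (11.9 against 2.27 FPKM), TSPYL5 (8.58 against 1.46 FPKM) and DPP6 (3.80 against 1.37 FPKM). The median of that list was 0.34, inside its wide random interval, and 0.49, outside, with the trend removed by the longest transcript.

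The other lists lay inside their random intervals with the deposited values. Medians were -0.08 for glycolysis, with GAPDH at 2219 and 2670 FPKM, and 0.24 for hypoxia, where ADM stood apart in HuES64 (38.4 against 101 FPKM). They were -0.07 for p53 targets, with CDKN1A at 83.0 and 104 FPKM, and 0.10 for the integrated stress and unfolded protein response, with ATF4 at 485 and 510 FPKM. Immediate early genes had a median of -0.20, and EGR1 (4.83 against 15.3 FPKM) and IER3 (12.9 against 36.0 FPKM) were at least 2-fold higher in HuES64. EGR1 overlaps another gene in the table. Genes of interferon response and antigen processing had a median of -0.17, with IFITM1 at 698 and 926 FPKM and IFI6 at 6.86 and 14.9. The WNT median was -0.04, with LGR5 higher in HuES53 (5.72 against 1.70 FPKM) and SP5 higher in HuES64 (1.41 against 4.74 FPKM). The replication-dependent histone median was -0.09, with HIST2H4A at 0.857 and 2.81 FPKM. Genes of 20q11.21, a region often gained in cultured stem cells, had a median of -0.05, with BCL2L1 (named outside the rule) at 56.5 and 52.2 FPKM. Housekeeping genes had a median of -0.18, with ACTB at 3040 and 3424 FPKM and EEF1A1 at 3188 and 4582. TPM scaling raised the list medians along with that of all genes, to 0.62 for core pluripotency, 0.59 for endoderm, 0.58 for cell cycle, 0.56 for heat shock, 0.48 for cholesterol synthesis, -0.39 for ribosomal proteins and -0.16 for fibroblast and mesenchyme genes. Relative to all genes these lists moved little, as from 0.34 to 0.36 for core pluripotency and from -0.66 to -0.64 for ribosomal proteins. The 10 negative medians among the lists inside turned positive with it, yet stayed below the median of all genes, as for glycolysis (-0.11 before and -0.09 after, relative to all genes). With the GC and length trend removed, 6 of them turned positive, those of immediate early (0.10), WNT (0.07), 20q11.21 (0.05), histone (0.03), neural crest (0.24) and maternally expressed imprinted genes (0.10), and the paternally expressed median turned negative (-0.04). Hypoxia genes lay outside with the trend removed (0.24), WNT (-0.17) and DNA methylation and Polycomb genes (0.22) did so by the longest transcript, and housekeeping genes (-0.17) did so against lists matched on GC content.

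**Figure D2:**
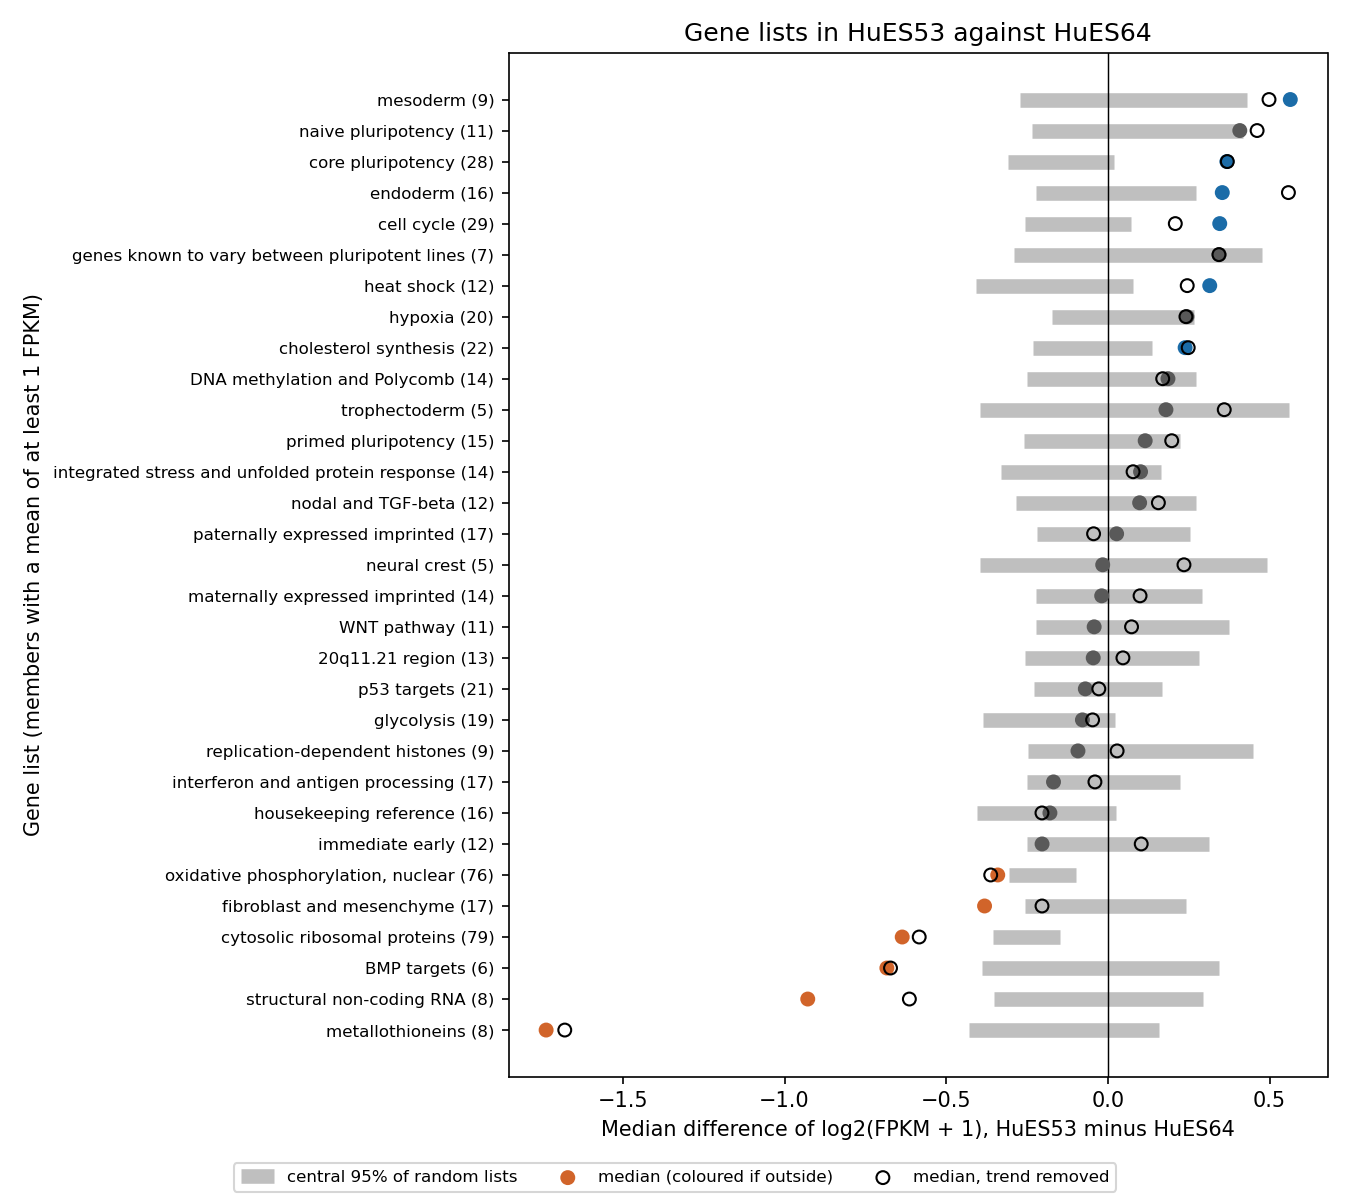
Median difference of log2(FPKM + 1), HuES53 minus HuES64, for 31 gene lists (filled points, blue above and orange below the random lists, grey inside), with the central 95% of random lists as grey bars, and the median after removal of the GC and length trend as open circles. The bars belong to the filled points, and the metallothionein list lies farthest out at -1.74.

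Among single genes, the largest differences above 0 in both lines fell on 15 genes in each direction. S100A14, which encodes a calcium-binding protein, stood at 99.0 FPKM in HuES53 and 5.14 in HuES64 (16.3-fold). ZFP57 differed by 13.2-fold, MEG3 by 6.85-fold, the protocadherin gene PCDHB5 by 6.52-fold (10.04 against 0.694 FPKM) and STC1, which encodes the hormone stanniocalcin, by 6.48-fold (48.1 against 6.58 FPKM). CER1, ZNF208 (13.8 against 0.869 FPKM) and ZNF676 (8.83 against 0.238 FPKM) were also on this side. Higher in HuES64 were PRAC (0.610 against 22.01 FPKM), GLIPR1L1 (0.141 against 5.87 FPKM), MT2A, WFIKKN1 (1.496 against 12.76 FPKM), NLRP2 and TEKT4P2, a pseudogene (0.0433 against 4.95 FPKM).

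The remaining genes of that ranking are uncertain. Overlap with another gene marked 8 of the 15 genes on the HuES53 side and 7 of the 15 on the HuES64 side. LOC100652751 (overlapping SCD), LOC100652937, LOC100653018 and TGIF2-C20ORF24 had a HuES64 value below that of 1 fragment, so they carry no fold. Fragments were reckoned over the whole locus, introns included, which overstates them for long loci. Other low values of long loci, such as that of EEF1E1-MUTED in HuES53, may thus also lie below 1 fragment. MUTED stood at 9.29 FPKM in HuES53 and 0.377 in HuES64, while the overlapping read-through genes EEF1E1-MUTED (0.00182 and 7.93 FPKM) and MUTED-TXNDC5 (0.518 and 7.49 FPKM) went the other way. CCDC169-SOHLH2 (10.97 and 0.223 FPKM), C1orf15-NBL1 (14.3 and 0.998 FPKM), DNAPTP3, which overlaps FN1 (3.71 and 87.3 FPKM), RPL36A and LOC388796 (9.25 and 73.0 FPKM) overlap other genes too. SNORD118, SNORA63, RNU1-1 and RNU1-8 have loci under 300 bases, and SNORD118 stood below 1 fragment in HuES53. Of the genes listed at 0 in the other line, all 5 on each side also had such short loci. These were MIR720 (181 FPKM), RNU6-15, MIR214, SNORA4 and SNORA27 in HuES53, and MIR3936 (295 FPKM), MIR7-1, SNORA72, SNORA11 and SNORA51 in HuES64. Of genes that were neither short nor overlapping, 200 were at least 2-fold higher in HuES53 and 125 in HuES64, out of 10007.

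Autosomes differed by small amounts that followed their GC content. Median differences ran from -0.17 for chromosome 22 to 0.23 for chromosome 4, and 15 of 22 autosomes lay outside their random gene sets, 9 above and 6 below. Chromosomes 4, 13 and 18 were highest (0.23, 0.20 and 0.18), and chromosomes 22, 19 and 16 were lowest (-0.17, -0.14 and -0.13). Across the 22 autosomes the median difference and the median transcript GC content had a Pearson's r of -0.97 and a Spearman's rho of -0.95, autosomes not being replicates. With the trend removed, 5 autosomes lay outside, and medians ran from -0.01 to 0.10.

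**Figure D3:**
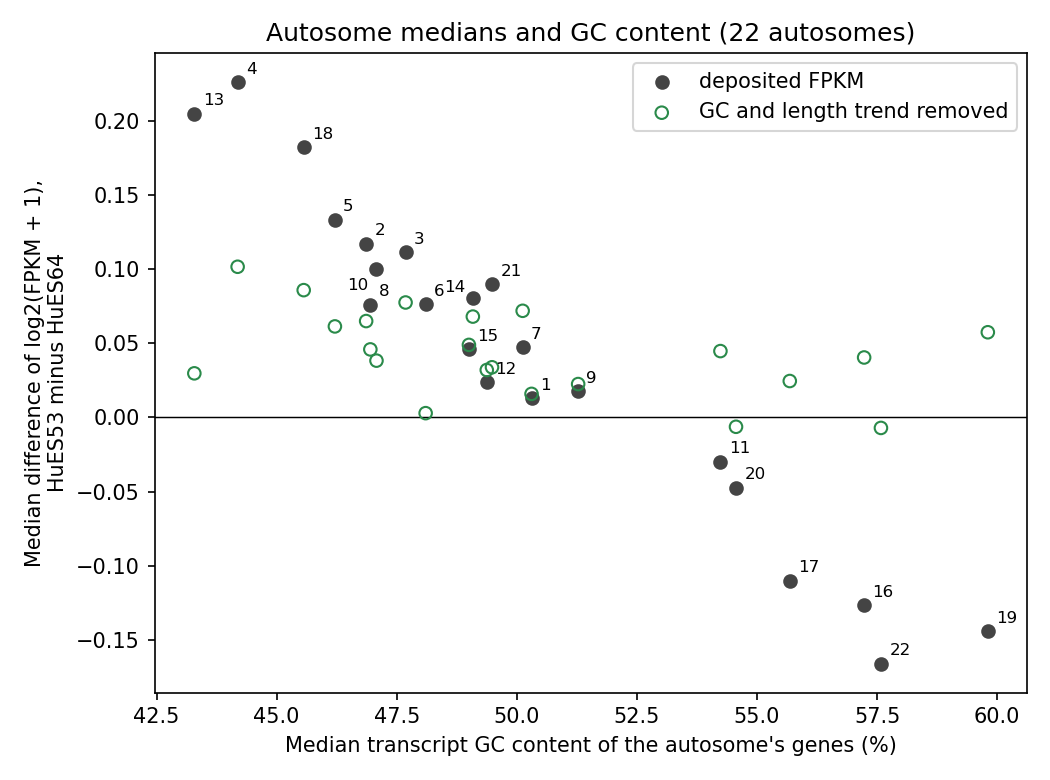
Median difference of log2(FPKM + 1), HuES53 minus HuES64, of the genes of each autosome (vertical) against their median transcript GC content in percent (horizontal), for 22 autosomes. Filled points use the deposited values and fall from 0.23 (chromosome 4) to -0.17 (chromosome 22), and open circles, with the GC and length trend removed, run from -0.01 to 0.10.

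Several zinc finger genes that are neighbours on chromosome 19 among the genes with a mean of at least 1 FPKM were higher in HuES53. The longest run of neighbouring genes at least 2-fold higher in HuES53 held 7 genes, between positions 22148897 and 23186010 of the deposited table, whose genome build is not given in the sources used here. They were ZNF208, ZNF257 (5.08 against 0.215 FPKM), ZNF676, ZNF729 (3.04 FPKM), ZNF98 (3.003 against 0.0633 FPKM), ZNF492 (2.64 against 0.0161 FPKM) and ZNF728 (2.65 FPKM). ZNF729 and ZNF728 were listed at 0 in HuES64. The run was looked for after the data were seen, and members other than ZNF208 and ZNF676 are named outside the fixed rule. Of 34 numbered ZNF genes with a mean of at least 1 FPKM from ZNF101 (start 19779663) to ZNF254 (end 24312654), 32 were higher in HuES53, with a median difference of 0.66, against 285 of 408 elsewhere (median 0.19). With the GC and length trend removed the counts were 26 of 33 (median 0.46) and 243 of 389 (median 0.10). These regional counts include the 7 genes of the run, which were picked for their difference. Without the run, 25 of 27 in the region were higher in HuES53 (median 0.48). With the trend removed this was 19 of 26 (median 0.35).

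**Figure D4:**
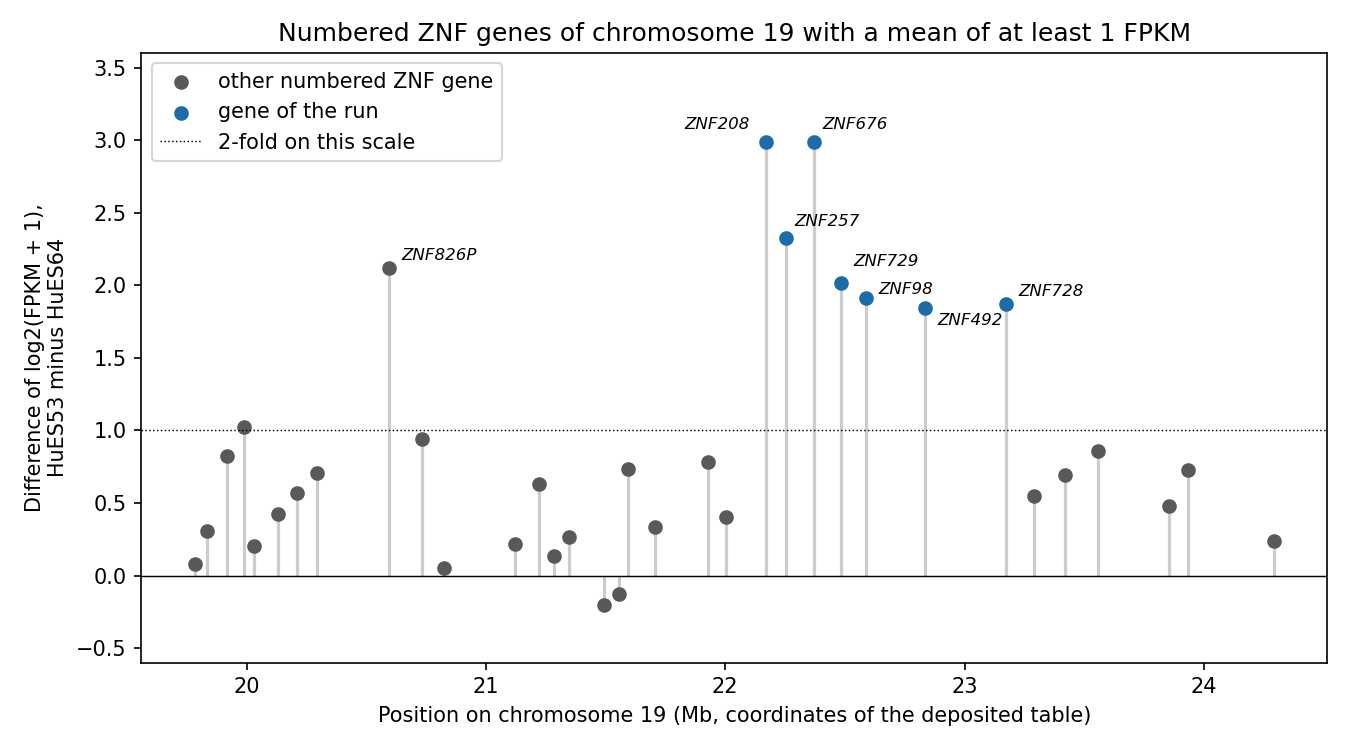
Difference of log2(FPKM + 1), HuES53 minus HuES64 (vertical), of 34 numbered ZNF genes by position on chromosome 19 in Mb (horizontal), with the 7 genes of the run in blue and 2-fold as a dotted line. The run stands between 1.84 (ZNF492) and 2.99 (ZNF208), and 32 of the 34 genes lie above 0.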

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

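The 12 gene lists outside their random lists kept their direction under every alternative that could be computed, and 10 of them stayed outside under all of them. The trend removals, the exclusion of short or overlapping loci and the matching on GC content were chosen after the data were seen. A pseudocount of 0.1 FPKM gave 585 genes at least 2-fold higher in HuES53 and 405 in HuES64, 107 and 85 at 4-fold, an r of 0.934 and a naive median of 0.59, then outside. With a pseudocount of 0.5 FPKM the naive median was 0.51, outside. Without a filter r was 0.977. A mean of at least 5 FPKM gave 161 genes higher in HuES53 and 159 in HuES64 from fewer genes tested (9661), so the lean to HuES53 was lost, with an r of 0.940, a fibroblast median of -0.33, no longer outside, and a maternally expressed imprinted median of -0.49, then outside. TPM scaling gave 774 genes higher in HuES53 and 200 in HuES64. With unmatched random lists the cholesterol median of 0.24 was no longer outside and the naive median of 0.41 was. Removing the GC and length trend, over the 11921 genes with a reference transcript, left 219 genes higher in HuES53 and 132 in HuES64 (245 and 170 for the same genes before) and 5 autosomes outside, and put naive (0.46), primed (0.20) and hypoxia genes (0.24) outside. Chromosome 6 moved from above to below its random sets at a median of 0.0029. With the longest transcript the counts were 231 and 108 at 2-fold and 50 and 27 at 4-fold, and 7 autosomes lay outside. Lists then outside were naive (0.63), primed (0.25), trophectoderm (0.64), WNT (-0.17), DNA methylation and Polycomb (0.22) and genes known to vary (0.49). Without loci under 300 bases, 29 and 20 genes passed 4-fold and r was 0.970. Without overlapping genes, 208 and 142 genes passed 2-fold, and 26 and 21 passed 4-fold. Lists matched on GC content put naive (0.44), hypoxia (0.24) and housekeeping genes (-0.17) outside and left 2 autosomes outside. Apart from fewer genes tested where a setting removes genes, the cause was not tested. Of the 70 named genes at least 2-fold different, 9 fell under 2-fold with TPM scaling and, with the trend removed, 11 of 58 (13 by the longest transcript), 1 when the highest row was kept, and none reversed under any alternative. Detection thresholds of 0.1 and 5 FPKM moved the counts of detected genes by under 1.5 times. Depth limits the low genes most: at 1 FPKM over 1 kb, HuES64 holds about 15.2 fragments. No paired analysis was possible because each line has 1 library.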

Other observations

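Some families of genes with a shared symbol stem leaned to one side. Families were formed after the data were seen, by the shortest start of a symbol that left only a number, then letters and digits if any (so PPP and PPP1R are separate), and 150 had at least 10 genes. Against 2000 random lists each, 24 lay outside with the deposited values and 28 with the GC and length trend removed. Chance would give 7.5 if genes varied independently, and may give more where genes of a family vary together. In both settings, 15 lay outside on the same side. Among them were RPL, RPS and MT genes, which largely repeat the fixed ribosomal protein and metallothionein lists. For the families named next, medians are given before and after removal of the trend. Higher in HuES53 were kinesin motor genes (KIF, 26 of 32 members, 0.34 and 0.22). KIF11 and KIF20A are also in the cell cycle list. So were DOCK genes, which encode exchange factors for small GTPases (10 of 10, 0.46 and 0.39). Synaptotagmin genes (SYT, 10 of 11, 0.54 and 0.40) and myosin genes (MYO, 13 of 15, 0.34 and 0.27) were higher too. Lower in HuES53 were the SNHG host genes of small nucleolar RNAs (-0.36 and -0.46, with 1 of 12 higher). TRAPPC genes of vesicle tethering (-0.36 and -0.26, with 4 of 12 higher) were also lower. The same held for RNA polymerase subunit genes (POLR, -0.24 and -0.14, with 10 of 30 higher). CD and TMEM genes (lower) were outside in both settings as well. So were SNORA and SNORD (lower) and MIR genes (higher), but their members went both ways. At least 2-fold higher in HuES53 and HuES64 were 18 and 18 of 59 SNORA genes. The counts were 4 and 5 of 10 SNORD genes, and 6 and 3 of 15 MIR genes. Among 125 loci under 300 bases, 36 and 43 genes passed 2-fold, against 261 and 192 of 13665 longer loci. Random lists were not matched on locus length, so lying outside says little for families of short loci. Of 442 numbered ZNF genes, 317 were higher in HuES53 and 22 were at least 2-fold higher there, against 0 in HuES64. The ZNF median of 0.22 was above its random lists, and with the trend removed it was 0.11, inside.

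The tests of summed ZNF and summed metallothionein values were chosen after related values had been seen, and the removal of the GC and length trend was not among the alternatives planned beforehand. One pattern is the set of opposite shifts of ribosomal protein, oxidative phosphorylation, core pluripotency and cell cycle genes. The trend over GC content and length does not account for the whole of any of the 4. With it removed the medians were -0.58, -0.36, 0.37 and 0.21, each still outside its random lists. For oxidative phosphorylation the values with the trend removed cover 61 of the 76 members, those with a matched transcript. By the longest transcript the oxidative phosphorylation median was -0.16, also outside. The trend could hold part of the difference for cell cycle genes (0.35 before) and, by the longest transcript, for oxidative phosphorylation genes (-0.34 before). For the autosomes the same trend may be the main source, as 15 lay outside before and 5 after its removal, but the test had asked for at most 3, so the rest cannot be told apart from a remaining GC effect. Growth state, culture conditions, RNA handling and a difference between the lines stay open for these shifts, untested with 1 library per line.

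For the run of 7 ZNF genes on chromosome 19, 0 of 10000 shuffles of gene order gave a run as long, and the longest had 4 genes. This argues only against a random order of genes that differ independently. Shuffling treats similar neighbouring genes as independent, and with 1 library per line it cannot measure chance differences between libraries. Every gene of the run was under 1 FPKM in HuES64, so each passed the filter through HuES53. The GC and length trend is argued against as the whole source by the median over the run, which was 2.02 before and 1.77 after its removal. A different split of reads among similar zinc finger genes would leave their sum about level. The summed FPKM of the region's 36 numbered ZNF genes was 1.74 times higher in HuES53 (253 against 146), before removal of the trend. Without the run it was 1.49 times higher. With the trend removed, over the expressed genes with a reference transcript, the ratios were 1.49 and 1.28. These sums follow from member values already seen, are no separate support and leave copies outside the region untested. Numbered ZNF genes elsewhere leaned the same way but less (285 of 408 higher in HuES53, median 0.19, and 0.10 with the trend removed). A shift of the whole region stays open, though the region was drawn around the run after the data were seen. Without the run, 25 of its 27 expressed ZNF genes were higher in HuES53 (19 of 26 with the trend removed, median 0.35). Elsewhere 243 of 389 were higher with the trend removed. Also open, untested, are a difference between the lines, a sequence that differs from the reference and culture history.

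Another pattern is the metallothionein difference, which stayed at a median of -1.68 with the GC and length trend removed, so the trend does not account for it. A different split of reads among the 9 listed genes would leave their sum level, but it was 3.22 times higher in HuES64 (1551 against 482), which follows from member values already seen, is no separate support and leaves copies outside the list untested. More zinc or another metal in the HuES64 culture is a candidate explanation, which predicted that SLC30A1, a zinc exporter gene under the same metal-sensing factor, would be at least 1.5-fold higher in HuES64. SLC30A1 was not: it stood at 4.76 FPKM in HuES53 and 3.23 in HuES64, a difference of 0.44, on the side that had been set beforehand as counting against the explanation. SLC30A1 is 1 gene in 1 library per line, and its difference lies within the standard deviation of all differences (0.56). That last condition was added only after the value was seen. The value alone therefore cannot decide for or against a metal effect.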
